A study of Mus musculus with 6 samples.

How the data were processed

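RNA of 6 cultures of Ba/F3 cells was measured on 6 Affymetrix arrays, 3 of cells with doxycycline and 3 of cells without, and the labels' titles gave each array its group and replicate number. Per the labels' protocols the RNA was checked on a NanoDrop and a Bioanalyzer and labelled with biotin using a 3′IVT PLUS kit. The values deposited by the authors are signal intensities on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.4.1, and the summary algorithm is not given in the sources used here. The values showed that each array had been scaled to a trimmed mean of 500, leaving out 2% at each end. No detection calls came with them, so the level of silent genes was described with a list of liver and brain genes. The labels call the cultures a triplicate and say nothing of separate experiments, so p-values measure only the spread between these cultures, and the number of arrays limits the precision.

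From the deposited intensities log2(signal + 16) was taken, with no further normalization. The 64 control probe sets were left out. Of the other 45037 probe sets the platform table gave exactly 1 gene symbol for 34945, several for 932 and none for 9160, and only the first were used, the probe set with the highest mean standing for its gene. This left 18193 genes, of which 9010 had more than 1 probe set. The symbols of 34741 probe sets matched the GRCm38.p6 gene table by Entrez number, 204 were kept unmatched and 0 had to be renamed. Near-identical members of gene families, such as the guanylate-binding proteins and immunity-related GTPases, can share probes, so their separate values are less certain than that of the group. For the named genes past the threshold, every probe set at or above the median level pointed the same way as the one used, although Sult2b1 had none at that level and the sizes differed.

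Induced and uninduced arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided, 4 residual degrees of freedom, Benjamini-Hochberg over all genes, threshold of 0.05) in R 4.3.3. A permutation test of 3 arrays against 3 cannot go below 0.10 and was not used for single genes. In all 36 gene lists were written before the data were examined, and the 35 with at least 5 measured genes were tested with camera at a preset correlation of 0.01. Of these, 16 passed, 7 higher and 9 lower. With the correlation estimated for each list 0 passed, the smallest adjusted p was 0.297 and 5 had an unadjusted p under 0.05, and with fry, which asks whether a list's genes move one way, 13 passed, 9 of them among the 16. In addition 4 lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

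The text names genes by a rule fixed before the data were examined. It takes up to 13 genes per direction with the largest change among those past the threshold, with no overlap between the groups and a mean of the higher group at or above the median of all probe sets, leaving out provisional symbols. It adds up to 4 members with the smallest p of each list described, lists of up to 12 genes in full, Jak2, Spag9 and every STAT5 target. Of the 34 genes past the threshold 30 met the first part, 18 higher and 12 lower, and 4 were left out by their symbols. Genes named outside the rule are said to be chosen after their values were seen.

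The procedure was tested on simulated data for the comparison of induced and uninduced cells, with the 18193 genes' own means and spreads and 200 changed genes in each of 5 runs. It called 45.6% of 2-fold changes, 84% of 4-fold, 95.6% of 8-fold and 97.6% of 16-fold changes, with 5.23% false among the calls, and a mean of 0 calls without any change. A list shifted by 1 was found in all 5 runs. The changed genes were drawn only from those at or above the median level, and the change was added to log2(signal + 16). The rates therefore do not cover dimmer genes. These simulated arrays vary independently and hold no array that stands apart.

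The alternatives set before the data were examined were a replicate block, median centring, quantile normalization, filters at the 25th percentile and at the median, the mean of a gene's probe sets or the most variable one, all probe sets, a trended and robust variance, no variance moderation, pseudocounts of 1 and 64, a threshold of 0.01, a test against a 1.5-fold change, an estimated correlation, fry, ranks, and leaving out each array. Under the 2 variance settings the lists were tested with cameraPR on the z-scores of those settings. Treating replicate 1 as a batch, leaving out both replicate 1 arrays, and averaging uninduced replicates 2 and 3 were added after seeing the data. Probe sets with no or several gene symbols are given only as counts, and genes without a probe set of their own were not analysed here.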

Results

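Gene expression was measured in Ba/F3 cells, a mouse pro-B cell line that depends on interleukin-3 for growth. The cells carried the SPAG9-JAK2 fusion, in which the tyrosine kinase JAK2 is joined to the scaffold protein SPAG9, under a promoter that doxycycline switches on. Cells were grown in triplicate with doxycycline at 500 ng/ml (induced, 3 arrays) or without it (uninduced, 3 arrays), and RNA was taken 48 hours later and hybridised to Affymetrix mouse 3′ expression arrays. Each array gave a signal intensity for 45101 probe sets, with median signals from 46.3 to 63.8, and 18193 genes were tested with 1 probe set each. Fold changes are differences of log2(signal + 16) between induced and uninduced cells, which understate the change of genes with low signal. The only comparison in the design asks which genes and pathways differ when the fusion is induced. No array held cells with doxycycline and without the fusion, and whether interleukin-3 was in the medium is not given in the sources used here.

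Induced cells had far more RNA of the guanylate-binding protein and immunity-related GTPase genes, families of interferon-inducible host defence proteins. Gbp2 rose by 6.61 ± 0.52 (log2 fold change ± SE), from a signal of 42.6 ± 33.1 (SD, n = 3) in uninduced cells to 5594 ± 2589 (SD, n = 3) in induced cells, with an adjusted p of 0.0304 in limma. Iigp1 rose by 6.26 ± 0.53, Gbp3 by 4.87 ± 0.43, Igtp by 3.93 ± 0.40, Irgm1 by 3.49 ± 0.39, Irgm2 by 3.21 ± 0.34 and Gbp7 by 2.62 ± 0.26. The other 6 named genes that rose were Zbp1, a sensor of Z-form nucleic acids (5.56 ± 0.57), Oasl2, an oligoadenylate synthetase-like protein (4.45 ± 0.48), Il18bp, a secreted protein that binds the cytokine IL-18 (from a signal of 30.9 to 739), Parp9, of the ADP-ribosyltransferase family (2.40 ± 0.27), Irf1, a transcription factor of interferon responses (2.28 ± 0.22), and Ube2l6, a conjugating enzyme for a ubiquitin-like modifier (2.19 ± 0.23). On uninduced arrays Gbp2, Zbp1 and Il18bp averaged 5.73, 5.93 and 5.50 on the log2 scale, below the 90th percentile of the liver and brain genes (5.99), a list that stood for background. The size of these 3 increases is therefore uncertain: with pseudocounts of 64 and 1 it was 6.04 and 7.16 for Gbp2, 4.69 and 6.06 for Zbp1 and 3.05 and 4.58 for Il18bp. Uninduced replicate 1 was the highest uninduced array for Gbp2 (6.59, against 5.03 and 5.56) and for Zbp1 (7.01, against 4.99 and 5.80), still far below the lowest induced array (11.50 and 10.83).

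The 12 named genes that fell came from several functions. Pi16, a secreted peptidase inhibitor family member, fell by 2.93 ± 0.24, from a signal of 310 ± 65.5 (SD, n = 3) to 26.8 ± 9.13 (SD, n = 3). Clec4e, a C-type lectin receptor of myeloid cells, fell by 2.47 ± 0.20, and Fbxl16, an F-box protein gene, fell by 2.47 ± 0.19. Bhlhe40, a transcription factor with hypoxia-responsive expression, fell by 2.32 ± 0.23. Cdkn2a, which encodes the cell cycle inhibitor INK4A and the p53 activator ARF, fell by 2.26 ± 0.24, from a signal of 769 ± 156 (SD, n = 3) to 149 ± 36.1 (SD, n = 3), with an adjusted p of 0.0396 in limma. The enzyme genes that fell were Pcx, pyruvate carboxylase (-2.17 ± 0.23), St3gal2, a sialyltransferase (-2.08 ± 0.24), Sult2b1, a sulfotransferase (-2.03 ± 0.22), Cda, cytidine deaminase (-1.69 ± 0.19), and Tgm2, a transglutaminase (-1.67 ± 0.16). That is the smallest change among the 6 probe sets of Tgm2, which ranged to -3.55. Igfbp6, which binds insulin-like growth factors, fell by 1.80 ± 0.17, and the cytokine gene Il16 fell by 1.63 ± 0.18. Induced arrays held Pi16, Fbxl16 and Sult2b1 at 5.40, 5.47 and 4.31 on the log2 scale, near or below the median of the liver and brain genes (5.43). The size of these decreases is therefore uncertain. For Sult2b1, with signals of 65.9 ± 14.3 (SD, n = 3) and 4.05 ± 3.78 (SD, n = 3), it went from -0.93 with a pseudocount of 64 to -3.95 with a pseudocount of 1.

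**Figure D1:**
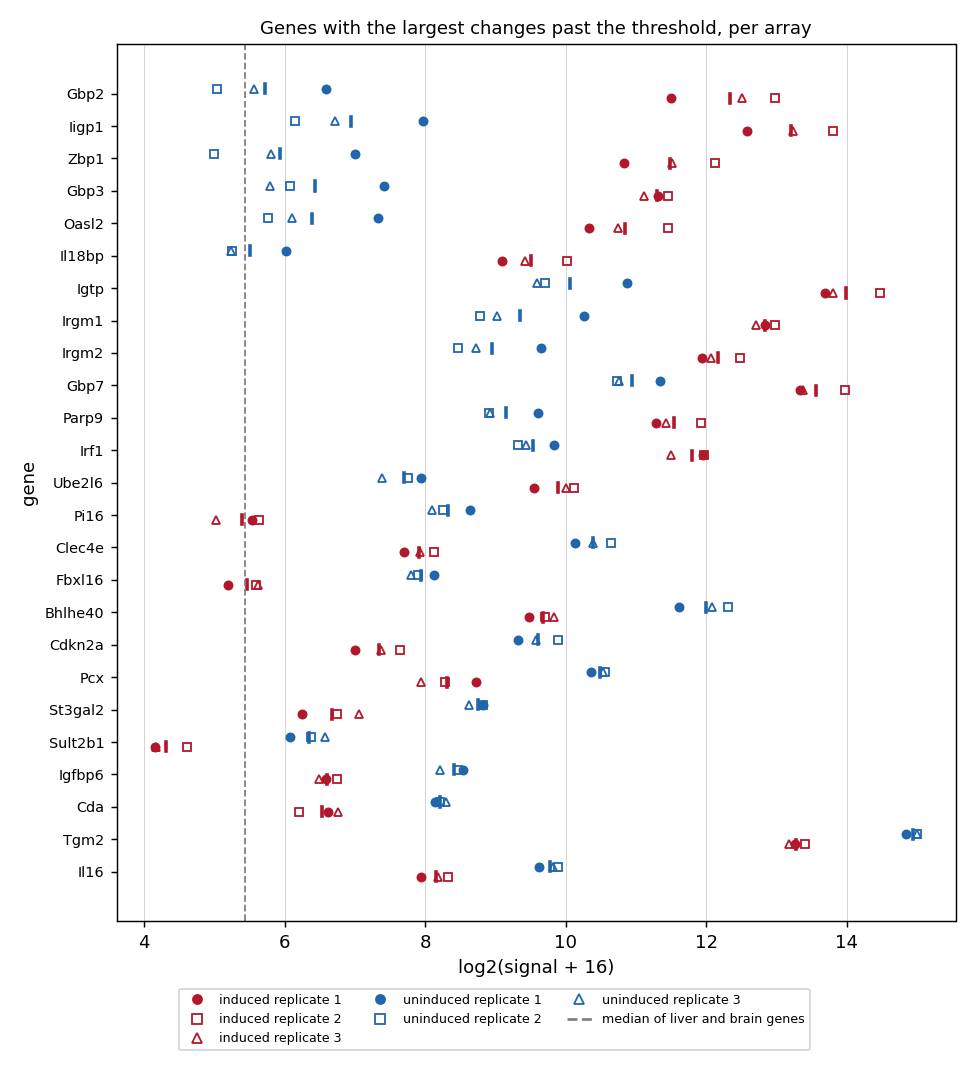
Level of each named gene on each array as log2(signal + 16), with induced arrays in red, uninduced arrays in blue, a short bar at each group's mean of 3 arrays and a dashed line at the median of the liver and brain genes (5.43). The groups do not overlap for any of these 25 genes, and for Gbp2 the induced arrays lie between 11.50 and 12.98 and the uninduced arrays between 5.03 and 6.59.

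In total 34 of 18193 genes passed an adjusted p of 0.05 in limma, 21 higher and 13 lower in induced cells, and all 34 had changed at least 2-fold. Their adjusted p ranged from 0.0206 to 0.0475. With each array centred on its median the counts were 24 higher and 6 lower, so that 80% of the calls were higher in place of 61.8%. Other choices gave more lower than higher genes: 198 of 342 with the filter at the median, 313 of 550 with trended and robust variance, 132 of 252 with a pseudocount of 64 and 867 of 1453 without uninduced replicate 1. So did 2 choices made after seeing the data, with 953 of 1477 without both replicate 1 arrays and 19 of 25 with replicate 1 as a batch. At an unadjusted p under 0.05 there were 1299 higher and 1872 lower genes. The direction of the majority is therefore not settled. For 4383 genes (24.1%) the 3 arrays of one group all lay above the 3 of the other, against 10% by chance. The count of 34 changed with single arrays: in limma it was 12 without induced replicate 1, 0 without induced replicate 2 (2224 at an unadjusted p under 0.05), and 1 without induced replicate 3. It was 1453 without uninduced replicate 1, and 0 without either uninduced replicate 2 (2093 unadjusted) or uninduced replicate 3 (2006 unadjusted). With a pseudocount of 1 in place of 16 it was 0 in limma (2816 unadjusted). With the replicate number as a block it was also 0 in limma (smallest adjusted p 0.198, 3269 unadjusted).

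The interferon-stimulated genes rose as a group. All 37 measured members had a positive log2 fold change, with a mean of 2.31 and a median of 2.02, and 8 passed over all genes and 32 when adjusted over the list alone (24 and 33 without uninduced replicate 1). The smallest p-values in the list were those of Gbp2, Iigp1, Gbp3 and Irf1. The list's camera test gave an adjusted p of 3.47e-30, and adjusted p = 0.297 with an estimated correlation. Its mean level was 11.13 ± 0.37 (SD, n = 3) on induced and 8.83 ± 0.62 (SD, n = 3) on uninduced arrays. Uninduced replicate 1 lay at 9.54, above uninduced replicates 2 and 3 (8.44 and 8.50), and the difference between groups was 1.27 in the arrays numbered 1 and 2.83 in those numbered 2 and 3.

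Genes of DNA replication and cell division were also higher in induced cells as lists. The G1/S list, which holds replication factors, had a mean log2 fold change of 0.52 over 43 genes, of which 40 were positive. None of them passed over all genes and 21 passed when adjusted over the list alone. Among its members were Mcm2, a subunit of the replicative helicase (1.06 ± 0.17), Cdc6, which loads that helicase (0.99 ± 0.18), Gins2 (0.92 ± 0.14) and Clspn (0.82 ± 0.15). The camera adjusted p was 2.57e-16, and adjusted p = 0.297 with an estimated correlation. The difference was 0.49 in the arrays numbered 1 and 0.54 in those numbered 2 and 3. The G2/M list of mitotic genes had a mean of 0.20 over 52 genes (camera adjusted p of 1.75e-05, and adjusted p = 0.297 with an estimated correlation), with 0 genes over all genes and, adjusted over the list alone, 4 higher and 1 lower. Nuf2, a kinetochore protein, stood at 1.31 ± 0.24, Tacc3 at 0.77 ± 0.17 and Tubb4b at 0.76 ± 0.16, whereas Psrc1, a spindle protein, stood at -1.25 ± 0.24. The direction of Tubb4b depends on the probe set, since its 5 others, of lower signal, gave from -0.34 to 0.37. The list's difference was 0.17 in the arrays numbered 1 and 0.22 in the others.

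Growth and mitochondrial lists moved the same way. The list of MYC targets and ribosome biogenesis genes had a mean of 0.50 over 43 genes, 40 of them positive, with 0 genes over all genes and 0 adjusted over the list alone (camera adjusted p of 2.0e-10, and adjusted p = 0.419 with an estimated correlation). Its members Odc1, the ornithine decarboxylase of polyamine synthesis, Rrp9, Bop1 and Ddx18 stood at 1.01 ± 0.30, 0.83 ± 0.23, 0.81 ± 0.20 and 0.57 ± 0.18. Uninduced replicate 1 (11.56) was level with the induced arrays (11.55 to 11.73) for this list, so the difference was 0.16 in the arrays numbered 1 and 0.67 in the others. The nuclear genes of mitochondrial translation had a mean of 0.31 over 64 genes (camera adjusted p of 6.51e-10, and adjusted p = 0.297 with an estimated correlation), with differences of 0.14 and 0.39 in the arrays numbered 1 and in the others. The mitochondrial ribosomal protein genes Mrpl20, Mrpl12, Mrpl16 and Mrpl40 stood at 1.26 ± 0.27, 0.91 ± 0.16, 0.84 ± 0.19 and 0.66 ± 0.15. The nuclear genes of oxidative phosphorylation had a mean of 0.17 over 66 genes (camera adjusted p of 7.07e-05, and adjusted p = 0.414 with an estimated correlation), with differences of 0.07 and 0.22, and Ndufa8, Ndufc1, Atp5g3 and Uqcr11 stood at 0.60 ± 0.15, 0.52 ± 0.16, 0.50 ± 0.15 and 0.50 ± 0.15. Neither mitochondrial list had a gene past the threshold over all genes or adjusted over the list alone (0 and 0). These counts depend on 1 array. Without uninduced replicate 1 the MYC list had 17 higher over all genes and, adjusted over the list alone, 31 higher and 1 lower. Mitochondrial translation then had 8 and 28 higher, and oxidative phosphorylation 2 higher and 1 lower over all genes and 0 over the list alone. Of the 16 heat shock genes Hsph1, a co-chaperone of HSP70, rose by 1.60 ± 0.17 and was the 1 member past the threshold over all genes, while 5 passed when adjusted over the list alone (6 and 9 without uninduced replicate 1). Dnaja1, Stip1 and Ahsa1 stood at 0.83 ± 0.15, 0.73 ± 0.16 and 0.69 ± 0.16. The heat shock list had a mean of 0.44 (camera adjusted p of 3.63e-06, and adjusted p = 0.297 with an estimated correlation), with differences of 0.30 and 0.52.

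Hypoxia, glucose metabolism and lysosome lists were lower in induced cells. The list of targets of the hypoxia-inducible factor HIF had the largest mean decrease of the fixed lists, -1.36 over 20 genes, 19 of them negative. In it 1 gene fell over all genes, Bhlhe40, and 13 fell when adjusted over the list alone (15 and 15 without uninduced replicate 1). Ddit4, an inhibitor of mTORC1, stood at -2.00 ± 0.31, Ero1a, an oxidase of the endoplasmic reticulum, at -1.95 ± 0.36 and Vegfa, an angiogenic growth factor, at -1.26 ± 0.20. The camera adjusted p was 4.32e-07, and adjusted p = 0.297 with an estimated correlation. The glycolysis and glucose uptake list had a mean of -0.60 over 19 genes, with 0 over all genes and 2 lower adjusted over the list alone (camera adjusted p of 0.000893, and adjusted p = 0.445 with an estimated correlation). Its members included Pdk1, which restrains pyruvate oxidation (-1.50 ± 0.47), the glucose transporter Slc2a3 (-1.12 ± 0.21), Pgk1 (-0.87 ± 0.27) and Pfkm (-0.78 ± 0.16). For Pdk1 the arrays numbered 1 were level (10.36 induced, 10.30 uninduced), and without them, a choice made after seeing the data, it stood at -2.28. The lysosome and autophagy list had a mean of -0.55 over 27 genes, with 0 over all genes and 4 lower adjusted over the list alone (camera adjusted p of 7.68e-05, and adjusted p = 0.414 with an estimated correlation). Lamp1, a lysosomal membrane protein, stood at -1.73 ± 0.30, Wipi1 at -1.62 ± 0.30 (its other probe sets gave from -1.66 to 0.16), Atg2a at -1.17 ± 0.29 and Gaa at -0.84 ± 0.19. In all 3 lists uninduced replicate 1 lay nearer to the induced arrays than uninduced replicates 2 and 3 did. In the arrays numbered 1 the differences were -0.58 for hypoxia, -0.11 for glycolysis and -0.30 for lysosome, against -1.75, -0.85 and -0.67 in the arrays numbered 2 and 3.

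Stress and growth arrest lists were lower as well. The list of ATF4 and amino acid response genes had a mean of -0.62 over 36 genes, with 0 over all genes and 10 lower adjusted over the list alone (camera adjusted p of 2.0e-05, and adjusted p = 0.414 with an estimated correlation). Ddit3, the stress transcription factor CHOP, stood at -2.24 ± 0.28, Pck2 at -1.31 ± 0.21 and Jdp2 at -1.17 ± 0.17, and Ddit4 is also a member. Here uninduced replicate 1 was the highest array (10.90, against 10.28 and 10.31 in uninduced replicates 2 and 3), the differences were -1.15 in the arrays numbered 1 and -0.35 in the others, and without both replicate 1 arrays, a choice made after seeing the data, the call was lost. The FOXO target list had a mean of -0.72 over 24 genes, with 0 over all genes and 6 lower adjusted over the list alone (camera adjusted p of 0.000565, and adjusted p = 0.297 with an estimated correlation, and differences of -0.42 and -0.87 in the arrays numbered 1 and in the others). Its members included Ccng2 (-2.45 ± 0.64), Txnip, an inhibitor of thioredoxin (-2.26 ± 0.28), Bbc3, the pro-apoptotic protein PUMA (-1.51 ± 0.22), and Insr (-1.02 ± 0.22). The p53 target list had a mean of -0.45 over 28 genes, with 0 over all genes and 6 lower adjusted over the list alone (camera adjusted p of 0.00147, and adjusted p = 0.297 with an estimated correlation, and differences of -0.38 and -0.48). Besides Bbc3 it held Trp53inp1 at -1.28 ± 0.28, Polk at -1.01 ± 0.21 and Mdm2, the ubiquitin ligase that degrades p53, at -0.85 ± 0.14, and its call was lost with the most variable probe set of each gene (mean -0.32). The size for Mdm2 depends on the probe set, since another with a mean level of 10.20, against 10.65 for the one used, gave -0.26.

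The 8 CDK inhibitor genes had a mean of -0.67, and 1 of them, Cdkn2a, fell over all genes and 2 fell when adjusted over the list alone, Cdkn2a and Cdkn2b (2 and 4 without uninduced replicate 1). The other 6 were Cdkn1a (-0.68), Cdkn2d (-0.38), Cdkn1b (-0.32), Cdkn2c (-0.25), Cdkn1c (-0.19) and Cdkn3 (0.05), and Cdkn2b stood at -1.34 ± 0.16. The camera adjusted p of the list was 0.00627, and adjusted p = 0.297 with an estimated correlation, with differences of -0.55 and -0.74. The list of ERK feedback and immediate early genes had a mean of -0.50 over 25 genes, with 0 over all genes and 0 adjusted over the list alone (camera adjusted p of 0.00448, and adjusted p = 0.445 with an estimated correlation, and differences of -0.49 and -0.51). In it the ERK phosphatase genes Dusp5 and Dusp6 stood at -1.67 ± 0.35 and -0.71 ± 0.19, Ier3 at -1.58 ± 0.48 and Phlda1 at -1.29 ± 0.30, and its call was lost without uninduced replicate 1 (mean -0.31). Granulocyte and monocyte markers had a mean of -1.09 over 23 genes, with 0 over all genes and 2 lower adjusted over the list alone (camera adjusted p of 0.000784, and adjusted p = 0.414 with an estimated correlation). Its members Ltf and S100a8, granule and calcium-binding proteins of neutrophils, stood at -2.27 ± 0.33 and -2.18 ± 0.47, Adgre1 at -2.18 ± 0.58 and Cd68 at -0.74 ± 0.20. Ltf and S100a8 averaged 4.62 and 4.88 on induced arrays, below the median of the liver and brain genes (5.43), so the size of their decrease is uncertain. The list's differences were -0.64 in the arrays numbered 1 and -1.31 in the others. With fry in place of camera 7 of the 16 lists did not pass: lysosome and autophagy (adjusted p of 0.0591), oxidative phosphorylation (0.0683), granulocyte and monocyte markers (0.0707), ATF4 (0.109), glycolysis (0.124), MYC targets (0.141) and ERK feedback (0.176). Without uninduced replicate 1 the lists with 0 over all genes had 15 higher (G1/S), 3 higher (G2/M), and 11 (lysosome), 10 (glycolysis), 8 (ATF4), 6 (FOXO), 4 (p53), 4 (granulocyte) and 1 (ERK) lower.

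**Figure D2:**
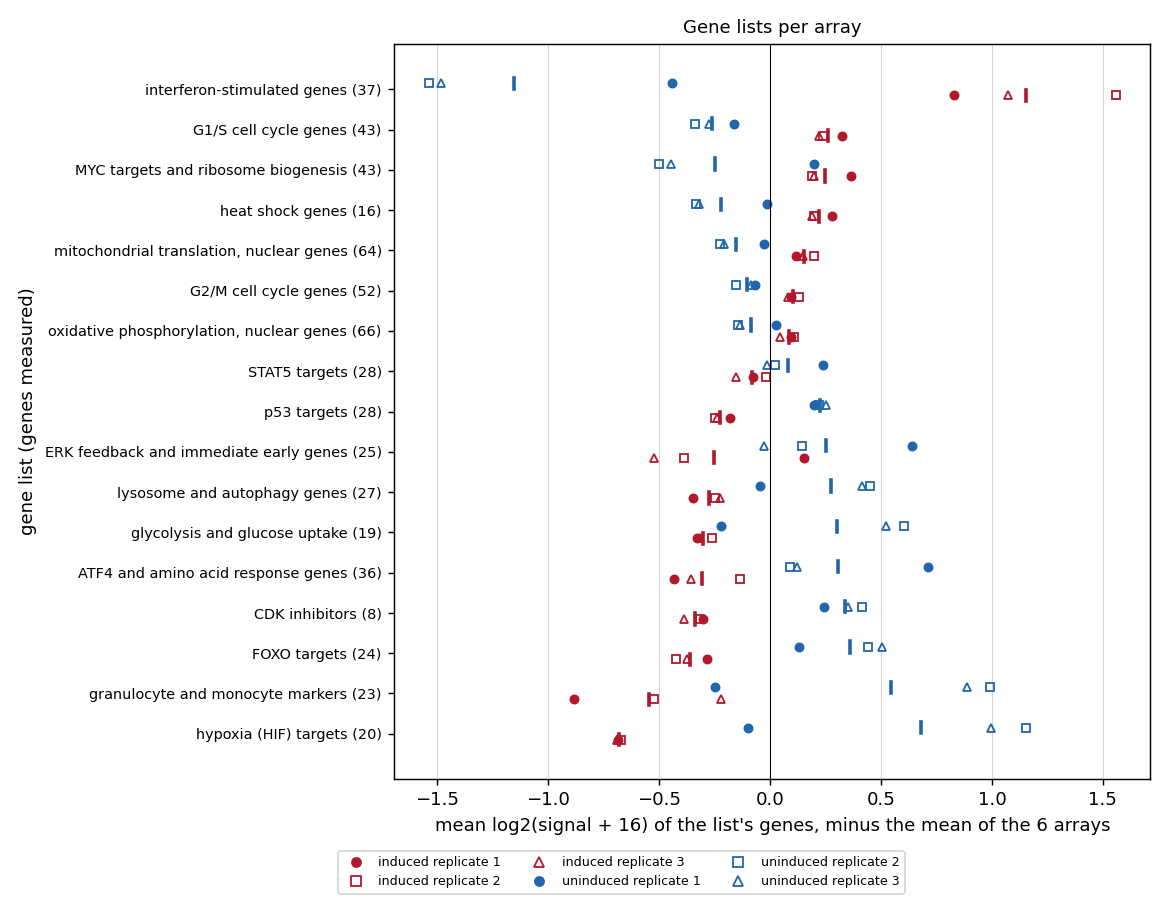
Mean log2(signal + 16) of each list's genes on each array, minus the mean of the 6 arrays, for the 16 fixed lists past the camera threshold and the STAT5 target list, with the number of genes measured in brackets, induced arrays in red, uninduced arrays in blue and a short bar at each group's mean. The interferon-stimulated genes part the groups most, with a mean difference of 2.31, and uninduced replicate 1 (filled blue circle) lies apart from the other uninduced arrays for most lists.

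The targets of STAT5, the transcription factor that acts below JAK2 in cytokine signalling, did not move together. The list had a mean of -0.17 over 28 genes (camera adjusted p of 0.677, and adjusted p = 0.743 with an estimated correlation), with 0 genes over all genes and, adjusted over the list alone, 1 higher and 1 lower. These were Socs1, an inhibitor of JAK kinases (1.39 ± 0.21, adjusted p of 0.0823 over all genes in limma), and Il2ra, the interleukin-2 receptor alpha chain (-2.33 ± 0.46, adjusted p of 0.109). None of the other 26 passed on either scale. Without uninduced replicate 1 the list's mean was -0.09, with 2 higher and 2 lower on each scale. The list's difference was -0.32 in the arrays numbered 1 and -0.09 in the others. The feedback genes Cish, Socs2 and Socs3 stood at -0.23 ± 0.33, 0.03 ± 0.24 and 0.60 ± 0.39, and the kinase genes Pim1, Pim2 and Pim3 at -0.53 ± 0.16, 0.16 ± 0.19 and -0.36 ± 0.30. The survival genes Bcl2l1, Bcl2 and Mcl1 stood at -0.05 ± 0.25, 0.13 ± 0.19 and 0.01 ± 0.23. The cell cycle genes Ccnd1, Ccnd2, Ccnd3, Cdk6 and Myc stood at 0.27 ± 0.23, 0.04 ± 0.29, 0.03 ± 0.27, 0.16 ± 0.20 and -0.08 ± 0.17. Probe sets of the survival and cell cycle genes differed. They ranged from 0.16 to 0.96 for Cdk6, -0.18 to 0.88 for Ccnd2, 0.02 to 0.82 for Bcl2 and -0.42 to 0.60 for Mcl1. The highest of these values came from probe sets of lower signal than the one used. Ccnd1, Ccnd3 and Bcl2l1 also changed sign between probe sets. The log2 fold changes of the rest were 0.97 for Osm, 0.38 for Bcl6, -0.04 for Id1, -0.12 for Spry1, -0.14 for Tnfrsf1b, -0.18 for Gimap6, -0.53 for Lta, -0.54 for Rnf125, -0.57 for Kit, -0.85 for Trib2, -0.88 for Il4ra and -1.38 for Fgl2. Bcl6, Gimap6, Kit, Lta, Spry1 and Trib2 averaged below the 90th percentile of the liver and brain genes (5.99) in both groups, so their values are uncertain.

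The JAK and STAT genes themselves had a mean of 0.20 over 10 genes (camera adjusted p of 0.669, and adjusted p = 0.783 with an estimated correlation), with 0 over all genes and 1 higher adjusted over the list alone, Stat2 (1.42 ± 0.24). Stat4 stood at 1.99 ± 0.84, Stat5a at 0.34 ± 0.17, Stat5b at -0.69 ± 0.25, Stat6 at -0.56 ± 0.21, Stat3 at 0.29 ± 0.24, Jak1 at -0.32 ± 0.26, Jak3 at 0.19 ± 0.21 and Tyk2 at -0.12 ± 0.20. Jak2 stood at -0.54 ± 0.41 (adjusted p of 0.542 in limma) and Spag9 at -0.92 ± 0.33 (adjusted p of 0.234). The labels do not say from which species the fusion was cloned or whether it holds the part that these probe sets bind, so neither value checks the induction. Several of these values rest on arrays that differ. In the arrays numbered 1 Stat4 was lower in induced cells (8.07 against 8.90) and Jak2 higher (10.50 against 10.22), and Stat5b (9.43 and 9.42) and Spag9 (11.13 and 11.13) were level. Without those arrays, a choice made after seeing the data, Stat4 stood at 3.41, Jak2 at -0.96, Stat5b at -1.04 and Spag9 at -1.37.

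The remaining 17 tested lists did not pass with camera, and none of their genes passed over all genes apart from Il16. Markers of B cells (mean -0.08, camera adjusted p of 0.887), of mast cells and basophils (-0.35, 0.677), of erythroid cells (0.29, 0.0930), of megakaryocytes and platelets (-0.44, 0.0610), of T and NK cells (-0.04, 0.960) and of fibroblasts and stroma (mean 0.00 and median -0.01, 0.823) were tested because Ba/F3 cells are of blood origin. Adjusted over the list alone, 0 passed for B cells, T and NK cells and fibroblasts, 3 higher and 2 lower for mast cells, 2 higher for erythroid cells and 1 lower for megakaryocytes. The cytokine receptors had a mean of -0.24 (0.0733), the NF-kB targets of -0.31 (0.216), the anti-apoptotic genes of -0.05 (0.873), the cytosolic ribosomal proteins of -0.04 (0.841), the cell adhesion and cytoskeleton genes of -0.20 (0.220) and the liver and brain genes of -0.06 (0.960), and 0 genes of each passed when adjusted over the list alone. The cholesterol synthesis genes had a mean of 0.02 and a median of -0.05 (0.791), with 0 adjusted over the list alone. The regulators of JAK and tyrosine kinase signalling had a mean of 0.02 and a median of -0.16 (0.960), with 2 higher adjusted over the list alone, and the chemokines and cytokines a mean of -0.16 (0.806), with 3 lower adjusted over the list alone. In the unfolded protein response list (mean 0.08, 0.129) 4 were higher and 3 lower adjusted over the list alone. The pro-apoptotic BCL2 family and caspases had a mean of -0.06 but a median of 0.10 and an upward test direction (0.224), with 2 higher and 2 lower adjusted over the list alone. With fry 4 of these lists passed, the cytokine receptors (adjusted p of 0.0158), the NF-kB targets (0.0158), the pro-apoptotic genes (0.0274) and the chemokines and cytokines (0.0317). Some passed with camera under other settings. Without uninduced replicate 1 these included the erythroid markers (mean 0.50, camera adjusted p of 0.0315) and the cell adhesion and cytoskeleton genes (-0.27, 0.0406). With the filter at the median they included the erythroid (0.55, 0.0229) and mast cell markers (-0.87, 0.0303). Of the mitochondrially encoded genes too few were measured for a test.

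The arrays did not split by group alone. The closest pair was uninduced replicates 2 and 3, whose log2 values differed by 0.141 (median absolute deviation over the genes at or above the median level), followed by induced replicates 2 and 3 (0.192). Uninduced replicate 1 differed from uninduced replicates 2 and 3 by 0.521 and 0.483, more than from induced replicates 1, 2 and 3 (0.339, 0.432 and 0.416). The first principal component held 40.6% of the variance and the second 23.6%. On the first, uninduced replicates 2 and 3 lay at 56.4 and 51.7, uninduced replicate 1 at -5.4 and the induced arrays from -36.2 to -31.4. The ratio of 3′ to 5′ signal of the Gapdh control was -0.61 ± 0.10 (log2, SD, n = 3) on induced and -0.42 ± 0.10 (SD, n = 3) on uninduced arrays, and that of the Actb control 0.35 ± 0.26 and 0.51 ± 0.15. The Actb ratio was highest on the arrays numbered 1, with 0.65 (induced) and 0.68 (uninduced) against 0.19 to 0.45 on the others.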

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

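The other splits of the arrays, median centring, quantile normalization and the fit of all probe sets were planned, and the other tests in this part, with the use of those scalings on the patterns below, were chosen only after the results were seen. The control probe sets for the mouse transferrin receptor, which the comparison of genes does not use, were higher on every induced array than on any uninduced array, by 1.78, 1.79 and 1.94 on the log2 scale for the 3′, 5′ and middle parts. The arrays numbered 1 lay closest, with 9.74, 8.61 and 7.81 on uninduced replicate 1 and 10.21, 9.32 and 8.45 on induced replicate 1. The gene itself, Tfrc, had a signal of 13878 ± 2774 (SD, n = 3) in induced and 5001 ± 1722 (SD, n = 3) in uninduced cells, with an adjusted p of 0.106 in limma. Other control probe sets were lower on every induced array than on any uninduced array. The largest such changes were those of mouse pyruvate carboxylase, -2.41 (3′ part), -1.42 (5′ part), -1.58 and -2.11 (middle parts). Its gene, Pcx, is among the named genes that fell. Among the 10092 probe sets with no or several gene symbols, also outside the comparison of genes, 1 was higher and 1 lower in induced cells when all probe sets were tested together.

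The 34 genes past the threshold, all changed at least 2-fold, and the 16 lists were compared with the other splits of the 6 arrays. In each case 1 of the 10 splits, the real one, gave as many, and the highest count of another split was 0 genes, 0 genes changed at least 2-fold and 11 lists. With 10 splits a share under 0.05 cannot be had, so these counts are too few to tell.

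The first pattern is the rise of interferon-stimulated genes. Array scaling is argued against, since the lower of the list's mean log2 fold changes after median centring and quantile normalization was 2.31. Interferon made by the induced cells stays open: the 8 interferon genes measured had a mean log2 fold change of -0.013 (median 0.04, test direction upward), but their mean levels of 4.82 and 4.83 lie below those of the liver and brain genes (5.53 and 5.59), where a change cannot be seen. An action of doxycycline itself cannot be told apart from that of the fusion, since 0 arrays held doxycycline without the fusion. That the fusion induces these genes, with or without secreted interferon, may therefore be kept as a hypothesis only.

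The second pattern is the distance of uninduced replicate 1 from uninduced replicates 2 and 3. RNA of induced cells mixed into it is argued against as the only difference. The implied share of induced signal was taken over list members changed more than 2-fold. Its median was 20.8% for 28 interferon genes (95% bootstrap interval over genes 7.64 to 29.7). For 14 hypoxia genes it was 92.2% (65.3 to 95.4), a gap of 71.4 percentage points that a mixture alone forbids. These shares assume that this array would otherwise match uninduced replicates 2 and 3, and the intervals treat genes as independent. A mixture together with another difference stays open. Array scaling is argued against as well. The distance leaves out the median shift between 2 arrays, so a single scaling factor hardly enters it. It was 3.56 times the one between uninduced replicates 2 and 3 as deposited, and 3.61 times after quantile normalization. A batch shared by the arrays numbered 1 stays possible: their deviations correlated at 0.173 over all genes, above every pair of unlike numbers, but only 1 array per group bears that number. Some control probe sets for bacterial genes, which the cells do not carry, also set these arrays apart. A bioC control (3′ part) read 12.31 (induced) and 12.43 (uninduced), against 11.55 to 12.07 on the others. A dap control (middle part) read 10.64 and 10.36, against 11.10 to 11.20. A thr control (5′ part) put them at opposite ends, 7.85 and 8.31. A shared difference in handling is thus likely, but its share of the distance cannot be told apart from culture differences. A culture that differed in density, age or medium could also add to the distance between the arrays' genes, and no such record was analysed here.

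The third pattern is the lower level of the hypoxia, glycolysis and lysosome lists in induced cells. Array scaling is argued against, since the value nearest to 0 of the 3 mean log2 fold changes after median centring or quantile normalization was -0.48. That the pattern is a state of uninduced replicates 2 and 3 alone cannot be told: the mean difference of the 3 lists in the arrays numbered 1 was -0.33, or 30.5% of the -1.09 in the arrays numbered 2 and 3, from 1 array per group. The lists were unlike in this: -0.11 against -0.85 for glycolysis, -0.58 against -1.75 for hypoxia and -0.30 against -0.67 for lysosome. The mean therefore does not stand for each of them, and the glycolysis difference was nearly absent in the arrays numbered 1. A denser or less aerated pair of uninduced cultures could give such values, and so could the fusion.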

How the results depend on the processing

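Replicate 1 as a batch, both replicate 1 arrays left out and uninduced replicates 2 and 3 averaged were chosen after seeing the data, and the other alternatives before. The 34 genes past the threshold, all changed at least 2-fold, became 30 with median centring, 28 with quantile normalization, 40 with the 25th percentile filter, 44 with the mean of probe sets and 25 with replicate 1 as a batch (12 shared with the 34). They became 19 with the most variable probe set, 17 with all probe sets, 3 (0 of them 2-fold, none among the 34) without variance moderation, 0 with a pseudocount of 1, 0 at a threshold of 0.01, 1 in the test against a 1.5-fold change and 0 with uninduced replicates 2 and 3 averaged. They became 342 (223 at least 2-fold) with the filter at the median, 550 (310) with trended and robust variance, 252 (153) with a pseudocount of 64 and 1477 (1032) without both replicate 1 arrays. Leaving out 1 array gave from 0 to 1453 genes (0 to 926 at least 2-fold), the highest without uninduced replicate 1, and from 16 to 18 lists. The causes were not tested. Unadjusted, 3171 genes had a p under 0.05, 2816 with a pseudocount of 1 and 1991 with the averaged arrays. The replicate numbers were not taken to pair the arrays, since over all genes deviations of same-numbered arrays correlated at 0.173, 0.078 and 0.084, although every array correlated best with its own number, a hint from the data and not the design. Over genes at or above the median level the values were 0.360, 0.193 and 0.331, but the arrays numbered 2 and 3 also correlated across numbers (0.188 and 0.297), so a pairing stays open. With the replicate block limma called 0 genes (smallest adjusted p 0.198, 3269 unadjusted), 0 at least 2-fold, and 16 lists. The number of lists was 13 with fry, 9 of the 16 and 4 others, and 0 with an estimated correlation. Under every other alternative it was from 15 to 18, at least 15 of them among the 16. All of those kept the preset correlation of 0.01, so their counts do not test that setting. The estimated correlation was 0.687 for the MYC list and 0.589 for the interferon list. None of the 16 lists and of the 26 named genes that passed changed sign, while lists that had not passed changed it in 32 cases and such genes in 48. All of those 26 genes but Hsph1 were named under a rule that required groups without overlap. Leaving out or averaging arrays therefore could not change their sign. The replicate block, replicate 1 as a batch and the variance settings leave the fold changes of genes and lists as they were. The estimated correlation, fry and ranks leave those of the lists as they were. No sign could change under these settings. Over the alternatives the 26 genes stayed past the threshold in 243 cases and not in 276, and the 16 lists in 342 and not in 26. Named genes that had not passed did so in 195 cases and such lists in 16. Genes near 5.43, the median of the liver and brain genes, in both groups have signal too close to background for a fall or a small rise to be measured.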

Other observations

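Genes of antigen processing for MHC class I were also higher in induced cells. In a list of 13 such genes chosen after the data were seen, 3 rose over all genes, Psmb10, an immunoproteasome subunit (2.14 ± 0.21), Tapbpl, a peptide editor (1.84 ± 0.18), and Erap1, a peptide-trimming aminopeptidase (1.73 ± 0.17), and 9 passed when adjusted over the list alone. The mean was 1.05 (camera adjusted p of 1.53e-10, and adjusted p = 0.0766 with an estimated correlation). Nlrc5, the transactivator of these genes, stood at 2.73 with an adjusted p of 0.0977. The list of 8 MHC class II genes had a mean of -0.41 and a camera adjusted p of 0.552, with 0 genes over all genes and 2 lower adjusted over the list alone, H2-Ob (-3.71) and H2-Oa (-0.80). The 9 measured guanylate-binding and immunity-related GTPase genes had a mean of 4.26, and 7 of them are among the genes that rose over all genes, so a test of that list would only repeat those calls. All genes and lists of this paragraph were chosen after their values were seen, and the p-values of the lists do not allow for that choice.

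Some of the genes that rose lay near each other in the genome, in a test chosen after the result was seen. Of the 34 past the threshold, 12 had another within 10 measured genes in the order of the GRCm38.p6 assembly, against a mean of 1.21 and a highest value of 11 in 10000 random draws. These were Gbp2, Gbp3 and Gbp7 on chromosome 3, Irgm1 and Gm12185 and, apart from them, Igtp and Irgm2 on chromosome 11, Parp9 and Parp14 on chromosome 16, and Iigp1, Gm4951 and BC023105 on chromosome 18. Shared probes between related neighbours may add to this count of 12, and this was not tested. Several of the 12 are guanylate-binding proteins or immunity-related GTPases, families whose called members lie side by side here. Draws of single genes do not allow for families that lie together, so the count adds little to the calls themselves.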
